A study of Homo sapiens with 4 samples.

How the data were processed

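The series holds 4 libraries of total RNA from A549, a human lung adenocarcinoma cell line, in 2 groups of 2. Cells of one group were transfected with U1 small nuclear RNA made by transcription in vitro, and cells of the other with RFP, as the labels name it. The labels do not say whether replicates came from separate cultures. The submitters' processing notes name the read trimmer fastp and the genome build hg38. The aligner, the counting tool and the annotation are not given in the sources used here.

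One table of the whole series was used. Its header gives a gene name, chromosome, region and Ensembl identifier per row, followed by 16 columns of values. Per the file headers, these are total counts, RPKM, TPM and CPM, 4 columns for each of 4 libraries called A21, A22, B19 and B20. A text search found 0 of the 4 codes in the sample labels or the series text, and neither the letter nor the number names a treatment. The 16 columns could therefore be assigned to no sample and to no group, and none of them entered any step. They were not assigned by their order, which no source ties to the samples, nor by their values, such as the level of U1 or of interferon-induced genes, which would have built the outcome into the groups. The library depths, the agreement between replicates and the difference between U1 and RFP are accordingly not analysed here. The comparison fixed before the data were examined, a quasi-likelihood test on the counts with 30 gene lists, was not run.

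The 4 annotation columns were read with Python 3.11.15 and pandas 2.3.3. Gene identifiers were matched without version numbers to the genes of GENCODE 29, an annotation of GRCh38 (hg38), and chromosome, start and length were compared. The comparison was run on simulated data in which 17559 of 58735 reference genes were moved by 50000 bases. It found the other 41176 unmoved. Identifiers, chromosomes and lengths were left as in the reference, and every moved gene had the same shift. The simulation therefore checked only the count of equal starts, not the matching of identifiers, the lengths or the shifts of neighbouring genes. Members of the 30 gene lists were looked up by current symbol, by the older symbol written beside it, and by gene identifier through a table of gene names. The parts of the naming rule that rank genes by test results could not be applied. The U1 genes of the list were named, as the rule sets, and its housekeeping controls were not. List members whose lookup failed, needed a second route or led to different rows were also named, chosen after the lookup was seen. A few interferon and interferon-stimulated genes were named only as examples, by no rule. The transcripts of U1 genes and pseudogenes in GENCODE 29 were compared with that of RNU1-1 by global edit distance (edlib 1.3.9.post1). Start positions are 1-based, as in the table and in the annotation.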

Results

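The series asked how U1 small nuclear RNA made in vitro affects gene expression in A549 cells. U1 is the RNA of the small nuclear ribonucleoprotein that recognises 5' splice sites. RNA was sequenced from 2 libraries of U1-transfected cells and from 2 libraries of RFP-transfected cells, the control. No expression level, fold change or depth is given for these libraries, because the codes that head the value columns could not be tied to a sample or a treatment. The results are limited to what the table covers: which genes it lists, where it places them, and how far the U1 genes can be told apart.

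The table listed 57773 genes with distinct identifiers and names on 25 chromosomes, the mitochondrial one included. By the gene types of GENCODE 29, 19263 of them were protein-coding, 6576 were long intergenic non-coding RNAs and 1803 were small nuclear RNAs. A further 5435 identifiers had no entry in that release. Small RNAs were thus part of the annotation, although the labels do not say whether the library protocol retained molecules of their size.

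All 19 U1 genes of the list fixed in advance were named in the table, 17 on chromosome 1 and 2 on chromosome 14. RNU1-1, RNU1-2, RNU1-3 and RNU1-4 encode the canonical U1 RNA. In the table, RNU1-1 (ENSG00000206652) lay on the minus strand of chromosome 1 from 16840617 to 16840780. RNU1-2 (ENSG00000207005) was placed on the plus strand from 17222475 to 17222638. RNU1-3 (ENSG00000207513) ran on the minus strand from 16993280 to 16993443, and RNU1-4 (ENSG00000207389) on the plus strand from 17067011 to 17067174. Each spans 164 bases and is annotated as a small nuclear RNA gene. RNU1-27P (ENSG00000206596) and RNU1-28P (ENSG00000206588) lay on chromosome 14, from 35015920 to 35016083 and from 35025432 to 35025595. The remaining 13 have names that begin with RNVU1 in the table and lie on chromosome 1.

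Several of these loci have one and the same transcript. Of 132 U1 gene and pseudogene transcripts in GENCODE 29, 7 had the sequence of RNU1-1, itself included. They are RNU1-1, RNU1-2, RNU1-3, RNU1-4, RNVU1-18, RNU1-27P and RNU1-28P, and all 7 identifiers have a row in the table. Reads within the 164 bases of these transcripts cannot be assigned to one of them by sequence, nor can reads of a transfected RNA with the same sequence be separated from the cell's own U1. The 6 U1 list members without an entry in GENCODE 29 had no sequence compared, so further rows may share that of RNU1-1. RNVU1-17 differed from RNU1-1 by 11 edits, RNVU1-6 and RNVU1-14 by 15 each, and RNVU1-15 by 18. The gene called RNVU1-2 both in the table and in GENCODE 29 (ENSG00000252135), of 135 bases, was farther away, at 62 edits, whereas the identifier that the table of gene names gives for RNVU1-2 (ENSG00000238825) is RNU1-13P in both, at 9 edits. So was RNU1-151P (ENSG00000201142), of 125 bases, at 65 edits, which the table calls RNVU1-8.

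Variant U1 names did not always point to one locus. Of the 127 compared transcripts whose gene identifier was in the table, 6 carried another name there. The gene called RNVU1-7 in GENCODE 29 (ENSG00000206585), 1 edit away from RNU1-1, was RNVU1-9 in the table, and the reference RNVU1-1 (ENSG00000207340), 6 edits away, was RNVU1-10. The table's own RNVU1-1 and RNVU1-7 had other identifiers, which were among 6 U1 list members without an entry in GENCODE 29.

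The gene lists fixed for RNA sensing, interferon, inflammation, stress, splicing, metabolism, growth and cell identity were almost fully covered. Of 660 distinct members, 659 were found by name or by identifier. All 50 interferon-stimulated genes, among them IFIT1, ISG15, MX1 and OAS1, had a row, as did all 22 interferon genes, including IFNB1 and the lambda genes IFNL1, IFNL2 and IFNL3. The 28 sensor genes were found as well, with RIGI, the receptor for RNA with a 5' triphosphate, under its older name DDX58. All 21 U1 and core snRNP protein genes and all 19 cleavage and polyadenylation factors were listed. The endothelial marker PECAM1 was found by neither route. Presence of a row says only that the gene was in the annotation, not that it was expressed.

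A symbol alone did not find 8 members, and 7 of these were found by identifier. These 7 were TLR9, TAP2, CFB, NDUFB8, SDHD, ITGB3 and TIGAR. Conversely, 7 members were found by name but not by the identifier that the table of gene names gives for their symbol. They are IKBKE, SOD2, CCL5, RNVU1-4, RNVU1-8, RNVU1-19 and RNVU1-20. Of the 645 members found by both routes, 640 led to the same row and 5 to different rows, RNVU1-1, RNVU1-2, RNVU1-3, RNVU1-7 and LUC7L2. Among the 19 U1 genes, 15 were found by identifier, and for 11 of these the name and the identifier led to the same row. In all, 2234 gene names in the table ended in a numbered suffix.

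The positions in the table were not those of GRCh38, the build that the submitters' processing notes name. Of 57773 identifiers, 52338 (90.6%) were in GENCODE 29, and 52312 of those were on the same chromosome in both. Only 365 of the 52312 (0.698%) had the same start, and the median difference between starts was 393776 bases. Gene lengths were the same in both for 42969 (82.1%). RNU1-1, at 16840617 in the table, starts at 16514122 in GRCh38. On chromosome 1 the table's genes reached 249231242, whereas the last gene of GENCODE 29 there ends at 248937043, and 9 genes of the table start past that point.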

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

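The alternatives for the expression comparison that were written before the data were examined (other normalizations, filters and tests, and leaving out each library) were not run, because the comparison itself was not. No paired analysis was possible because the value columns carry no replicate number and could not be tied to samples. The settings that follow were chosen after seeing the data. Looking up the list members by current symbol alone found 641 of 660, and by gene identifier alone 652, against 652 by current or older symbol. The start was that of GRCh38 for 365 of 52312 identifiers, and it lay within 10000 bases of it for 3106 (5.94%). Counting U1 transcripts within 10 edits of RNU1-1 gave 13, against 7 with its exact sequence, RNU1-1 itself included in both. Sequencing depth limits none of these values, since no read count entered them.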

Other observations

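The test in this part was chosen only after the mismatch of coordinates had been seen. A different release of a GRCh38 annotation would revise gene models one by one, so that moved genes would rarely share a shift. Of the 42969 identifiers with the same length in both annotations, 42647 started elsewhere. Of these, 94.7% were shifted by exactly as many bases as the previous such gene on the chromosome, which argues against that explanation. Shifts shared by neighbours are consistent with an annotation of another genome assembly. A candidate is the earlier GRCh37, but no GRCh37 annotation was used here, so this stays untested. Whether the reads were aligned to the assembly of the table or to hg38 also stays open.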
